A study of Danio rerio with 22 samples.

How the data were processed

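Ribosome footprints (fragments of mRNA protected by ribosomes, RPF) and input mRNA had been sequenced from whole zebrafish embryos at 2, 4 and 6 hours post-fertilization (hpf). The embryos were wild type or MZdicer, mutants that lack the microRNA-processing enzyme Dicer from both the egg and the embryo. There were 22 libraries, 12 of footprints and 10 of input, in 12 groups of library type, genotype and stage, of which 10 groups held 2 libraries and 2 groups held 1 (MZdicer input at 2 and at 6 hpf). Per the labels, embryos were treated with cycloheximide, lysates were digested with RNase I, and the protected fragments were taken through a sucrose cushion and a size-selecting gel into barcoded small-RNA libraries. The labels give input as polyA RNA and name the background TUAB for the input libraries of both genotypes. Wherever mRNA level is named below, it is thus the level of polyA RNA. The labels do not say whether replicates came from separate clutches, so each p-value measures spread between samples, which covers technical spread at the least.

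The deposited values are unstranded signal, a scaled read coverage per base over intervals of the Zv9 (danRer7) genome, and the authors named TopHat 1.2.0 as the aligner. Every value tested, up to 20 steps, was a whole multiple of 1 step per library within 0.1 of a step, so each value was divided by that step to give read equivalents. The scale, filters and treatment of reads with several placements were not stated, and regions with identical profiles in every library of a type were found at different positions. Reads per library were counted as increases of coverage at left ends, and distinct left ends as the positions with an increase. These reads are not independent molecules, and floors cover counting error only.

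Neither a genome sequence nor an annotation of the Zv9 build was at hand, so features were regions without gene names. Covered intervals of all libraries were joined across gaps of up to 50 nt into 1155825 regions (median length 27 nt), and the read equivalents of a library in a region were its summed coverage in steps divided by the median width of that library's isolated covered blocks (27 to 32 nt in footprints, 23 to 25 nt in input). Mitochondrial regions were left out. The planned tests on genes with miR-430 seed sites, on fixed gene lists and on dicer1, and the planned counting over coding exons or over all exons, were not run for lack of an annotation.

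The plan made before the data were examined assumed read counts and a test on counts. Since the files hold scaled coverage, limma 3.58.1 in R 4.3.3 was used in its place, on log2 of scaled read equivalents plus a pseudocount of 2. Regions with at least 10 read equivalents in at least 2 libraries of a type were tested, which left 90008 regions in input, 28562 in footprints and 25723 in both. Libraries were scaled by a trimmed mean of log ratios (trim 0.3 of ratios and 0.05 of levels). Group means were fitted over all libraries of a type, and over all 22 libraries for translation efficiency (TE, the footprint change minus the input change, log2), with a trended and robust prior and equal library weights. Calls had a Benjamini-Hochberg adjusted p under 0.05. Both groups of a comparison share the spread of all groups, and a group of 1 library was assumed to vary like the others. The robust prior was the setting planned before any fit, and fits with other priors, pseudocounts, library weights and feature sizes had also been looked at before the settings were settled.

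The rule for naming regions was fixed before the data were examined. It took, per comparison, up to 8 regions with the largest rise and 8 with the largest fall among those called, with a mean of at least 10 scaled read equivalents (in place of a threshold on counts, as the files hold none) and no overlap between the libraries of the groups. The condition on overlap was not applied to TE. Levels are mean scaled read equivalents, followed by the range of the libraries where it is given, and errors of log2 changes are standard errors (SE). A fold against a group with all libraries at 0 was computed against a floor of 3 read equivalents per library, scaled as that library and averaged over the group, and is written as a lower bound. A log2 change against a level under that floor depends on the pseudocount. Loci of calls are regions less than 10000 nt apart.

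Sets of regions were compared with all other regions by camera (limma) with a preset correlation of 0.01, with the p from an estimated correlation beside it, and 41 such tests were adjusted together. The sets were devised after the data were seen, in place of the planned target genes. The set used most holds regions at least 2-fold higher in MZdicer than in wild-type input at 6 hpf at an unadjusted p under 0.01. Of this set, 3 definitions were looked at. The footprint libraries had no part in that fold or p. The input libraries of earlier stages entered the p through the spread shared by all groups. Tests of the set in input and in TE are thus not fully separate from its selection.

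The procedure was tested on simulated data with the median spread of each library type, drawn independently for each region and library. Changes of 16-fold were recovered in 71% to 80% of cases in footprints between genotypes, 0% to 35% in input and 3% to 16.3% in TE. Changes of 4-fold were recovered in 3% to 10%, 0% to 2% and 0% to 1.02% of cases. A simulated set shifted by 0.6 (log2) was recovered as 0.60, with p = 2.38e-05 under an estimated correlation, and an unshifted set gave -0.03 (p = 0.83 under the same). Simulated regions were independent, whereas the estimated correlation within the set used most was 0.19 in footprints. The simulation thus does not show the power of that test for regions that vary together.

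Alternatives were another scaling (median of ratios, or the deposited scale), pseudocount, prior, library weights, distinct left ends in place of reads, regions split at gaps of 20 nt, loci chained across 2000 nt, no filter on low values, a fit of the compared groups alone, a replicate block, and each replicate left out. A count under another setting is a new count and need not hold the same regions. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 built the regions, and matplotlib 3.10.9 drew the plots.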

Results

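Ribosome footprints and input mRNA were measured in whole zebrafish embryos of 2 genotypes at 2, 4 and 6 hpf. Footprints had 2 libraries in each of the 6 groups of genotype and stage. Input had 2 libraries per group except for MZdicer at 2 hpf and at 6 hpf, which had 1 each. The footprint libraries held 1944433 to 12285440 reads and the input libraries 3593323 to 13502217, counted from left ends of covered blocks. Distinct left ends numbered 71422 to 1045318 in footprints and 91538 to 2196698 in input. The sparsest against the median of their type were MZdicer footprints at 6 hpf replicate 2 (71422), MZdicer input at 2 hpf (91538, against 1355621 and 1368935 in wild type) and MZdicer input at 4 hpf replicate 2 (231807). Isolated covered blocks had a median width of 27 to 32 nt in footprints and 23 to 25 nt in input. A block on chromosome 4, from 61288251 to 61302520, held 47.1% to 87.8% of footprint coverage and 18.7% to 54.1% of input coverage. The ratio of left ends 3 nt apart to those 2 and 4 nt apart was 1.00 to 1.03 in footprints and 1.01 to 1.04 in input. This measure thus did not separate a 3-nt step of the ribosome from background. It counted distinct, unstranded positions of reads of all widths without coding frames, so it could miss such a step and does not show that it was absent.

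**Figure D1:**
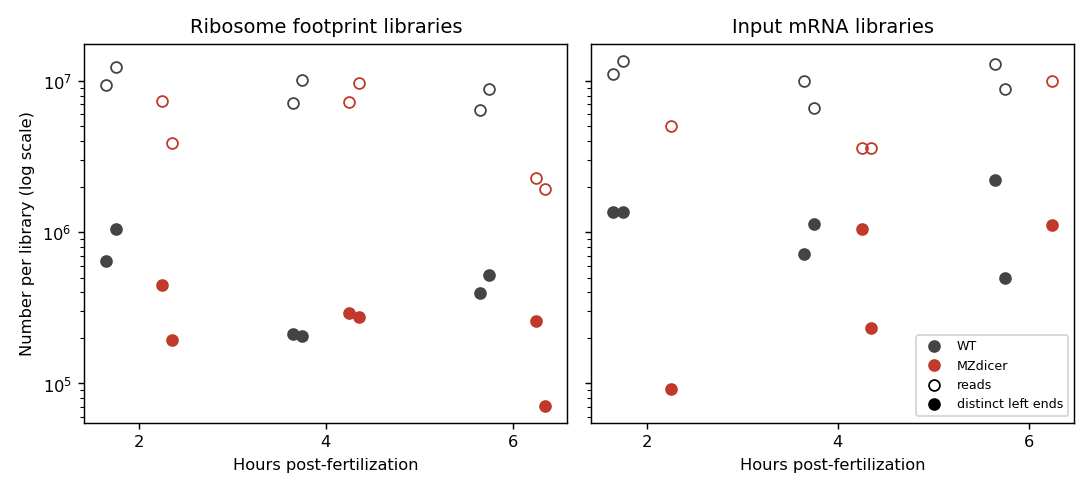
Reads (open circles) and distinct left ends (filled circles) of each library on a log axis, by hours post-fertilization, for footprints at left and input at right, with wild type in grey and MZdicer in red. MZdicer input at 2 hpf had 91538 distinct left ends against 1355621 and 1368935 in wild type.

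The comparison of genotypes in input asks which mRNAs differ in level in embryos without Dicer. At 6 hpf, the regions with the largest rise in MZdicer input stood at low levels in wild type, which a ranking by fold favours. The region from 31225539 to 31227069 on chromosome 14 had 94.7 scaled read equivalents in MZdicer and 0 in both wild-type libraries, at least 32.3-fold higher. The region from 28026526 to 28027113 on chromosome 2 had 178 against 3.53 (0 to 7.05; log2 change 5.40, SE 0.71), that from 13640033 to 13640353 on chromosome 21 had 495 against 7.58 (1.61 to 13.6; 6.05, SE 1.2), and that from 27574249 to 27575335 on chromosome 18 had 163 against 3.54 (0 to 7.08; 5.27, SE 0.88). A pair of regions with identical profiles, at 31836260 to 31836791 on chromosome 2 and 25385441 to 25385972 on chromosome 23, had 502 against 15.2. Among the lower regions, that from 1123341 to 1124952 on chromosome 6 had 0 in MZdicer against 410 (270 to 551), at least 195-fold lower, and that from 26383716 to 26384756 on chromosome 18 had 0 against 284, at least 135-fold lower. In all, 61 regions in 47 loci were higher and 4 regions in 4 loci lower of 90008 tested with limma, and 5839 regions had an unadjusted p under 0.05, against 4500 expected by chance. MZdicer had 1 input library at this stage, 18.3% of whose coverage was mitochondrial against 15.7% and 12.3% in wild type. The total of 65 calls was 2 with a prior that was not robust, 0 in a fit of the compared groups alone, 19 without wild-type replicate 1, 1 without wild-type replicate 2 and 120 on the deposited scale. Counted over distinct left ends, 178 regions were higher and 120 lower.

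At 4 hpf, few input regions differed between genotypes. The region from 1123341 to 1124952 on chromosome 6 was already lower in MZdicer, at 3.86 (0 to 7.72) against 344 (341 to 347; log2 change -6.29, SE 1.02), and so was that from 26383716 to 26384756 on chromosome 18, at 3.86 against 241 (-5.78, SE 1.04). On chromosome 17, 3 regions between 19252362 and 19270838 were lower, led by that from 19252362 to 19254126 with 0.729 against 145 (-5.78, SE 0.76). A 27-nt region on chromosome 15, from 32602104 to 32602130, had 25.2 against 1068 (-5.77, SE 0.87) and was the reverse at 6 hpf, with 1825 against 19.4 (6.89, SE 1.07). The region from 35888279 to 35888302 on chromosome 22 was higher in MZdicer, at 484 against 3.05 (6.48, SE 1.15). In all, 1 region was higher and 6 regions were lower, and 6404 had an unadjusted p under 0.05. The total of 7 calls was 252 without MZdicer replicate 1, 0 without MZdicer replicate 2, 0 without wild-type replicate 1 and 0 with a prior that was not robust. Without wild-type replicate 2 the split was the reverse, with 8 higher and 0 lower.

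At 2 hpf, 7448 input regions were lower and 644 higher in MZdicer, and the median change over all regions was -1.56. The region from 22244570 to 22245330 on chromosome 10 had 0 in MZdicer against 363 (356 to 370) in wild type, at least 155-fold lower, and that from 42069001 to 42070565 on chromosome 21 had 0 against 579 (511 to 647), at least 248-fold lower. The region from 17190596 to 17190961 on chromosome 10 was higher, with 4013 against 6.39 (2.48 to 10.3; log2 change 9.08, SE 1.36). The MZdicer group was the single library with 91538 distinct left ends, and 60.2% of the tested regions stood at 0 in it. The total of 8092 calls was 3064 without wild-type replicate 1 and 3425 without wild-type replicate 2. With no filter on low values the balance was reversed, with 4211 higher and 1590 lower.

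In footprints, the comparison of genotypes asks where footprint coverage differed. At 2 hpf, 13 regions were higher in MZdicer and 0 lower, among them short regions with shared profiles, and 7 were up to 60 nt long. The regions named here had too little input to be tested there, so their footprints cannot be tied to mRNA. A profile shared by 3 regions, at 31403618 to 31403656 and 43535909 to 43535947 on chromosome 4 and at 538931 to 538969 on the unplaced sequence Zv9_scaffold3530, had 1686 (1457 to 1916) in MZdicer against 34.8 (30.5 to 39.2; log2 change 5.52, SE 0.62). It was also higher at 4 hpf, with 7784 (7737 to 7830) against 366 (231 to 501), and at 6 hpf (log2 change 3.75, adjusted p = 0.0207). Another shared profile, at 30787356 to 30787396 on chromosome 22 and at 1660400 to 1660440 on chromosome 3 among others, had 475 against 4.21 (6.43, SE 0.89). The 13 regions had 8 distinct profiles, and 949 of 28562 regions had an unadjusted p under 0.05 with limma, against 1428 expected by chance. Without MZdicer replicate 1 there were 0 higher and 1 lower, without MZdicer replicate 2 there were 3 higher and 0 lower, without wild-type replicate 1 there were 10 and 2, and without wild-type replicate 2 there were 5 and 3. A fit of the compared groups alone gave 0 calls.

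At 4 hpf, 20 footprint regions were higher and 14 lower in MZdicer. Higher were repeats on chromosome 4, such as the profile shared by 31657590 to 31657627 and 41776767 to 41776804 (111 against 0.470, log2 change 5.51, SE 0.96), and the region from 49052435 to 49052722 (259 against 6.56, 5.02, SE 0.86). Lower were the region from 3367198 to 3367379 on chromosome 20, with 1.93 against 254 (232 to 277; -6.06, SE 0.72), that from 11460177 to 11460467 on chromosome 11, with 2.93 against 620 (333 to 907; -6.82, SE 1.01), and that from 1127680 to 1128041 on chromosome 6, with 0 against 130, at least 35.6-fold lower. The chromosome 6 region from 1123341 to 1124952, lower in input, was itself lower in footprints at 4 hpf (-4.82, adjusted p = 0.045) and 6 hpf (-4.94, adjusted p = 0.032). The higher regions had 14 distinct profiles and the lower ones 10, and 2726 regions had an unadjusted p under 0.05. Up to 60 nt long were 12 of the higher and 9 of the lower regions. Of the 24 distinct profiles called, 8 had enough input to be tested there. The deposited scale gave 7 higher and 9 lower, and there were 0 calls without either MZdicer replicate, 3 higher and 0 lower without wild-type replicate 1, 3 higher and 6 lower without wild-type replicate 2 and 0 in a fit of the compared groups alone.

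At 6 hpf, 24 footprint regions were higher and 32 lower in MZdicer. On chromosome 10, the region from 35936475 to 35936701 had 317 (279 to 355) in MZdicer against 15.6 (10.6 to 20.7; log2 change 4.23, SE 0.57), and its neighbour from 35939024 to 35939322 had 125 against 7.32 (4.13, SE 0.72) and was also higher in input (4.46, adjusted p = 0.0015). The region from 774415 to 775249 on chromosome 1 had 383 against 27.3 (3.99, SE 0.67) and that from 839743 to 840903 on chromosome 19 had 79.4 against 4.24 (3.95, SE 0.63), and both were higher in input too (3.72 and 3.60). Lower were again the chromosome 20 region from 3367198 to 3367379 (0.668 against 231, -6.45, SE 0.72) and, on chromosome 18, that from 27853429 to 27853664 with 0 against 200 (53.2 to 346), at least 21.4-fold lower. Of the 54 regions higher in MZdicer input at 6 hpf that were tested in both types, 9 were also called higher in footprints, against 0.0420 expected if the calls were independent. Up to 60 nt long were 4 of the higher and 18 of the lower footprint regions, and the chromosome 20 region had too little input to be tested there. The median change in footprints was -0.31, and 3500 regions had an unadjusted p under 0.05. The split was 11 higher and 25 lower with median-of-ratios scaling and 0 with the deposited scale. There were 509 higher and 1577 lower without MZdicer replicate 1, 5 and 2 without MZdicer replicate 2, 0 calls without wild-type replicate 1, 5 higher and 4 lower without wild-type replicate 2 and 0 calls in a fit of the compared groups alone, and in simulated data 27 of 117 calls in this comparison were false.

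**Figure D2:**
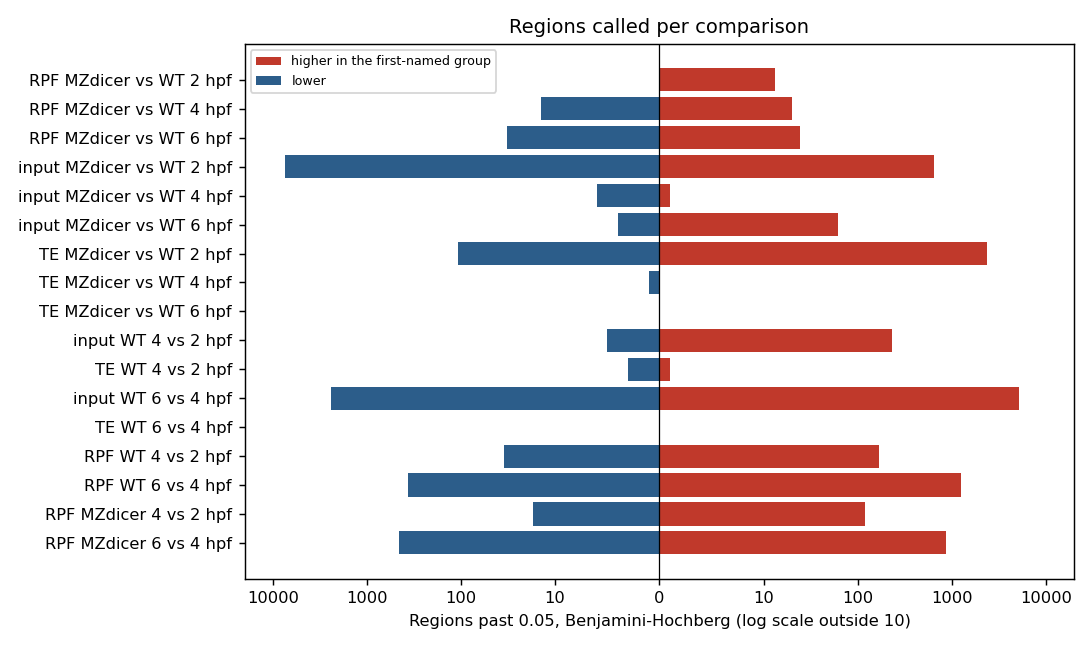
Regions called per comparison (adjusted p under 0.05, limma), higher in the first-named group at right in red and lower at left in blue, on an axis that is logarithmic outside 10. MZdicer input at 2 hpf, 1 sparse library, had 7448 lower regions, against 6 at 4 hpf and 4 at 6 hpf.

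Regions higher in MZdicer input at 6 hpf were followed back to earlier stages, to ask whether footprints or mRNA differed first. This set of 547 regions in 384 loci was devised after the data were seen. At most 129 such regions were expected by chance, and 92.1% of the set had at least 10 scaled read equivalents in wild-type input at 2 hpf, against 85.5% of all regions tested in both types. Set footprints at 4 hpf were 1.53-fold higher in MZdicer relative to other regions (log2 difference 0.61, 380 of 547 regions above the median of other regions, adjusted p = 4.86e-09), while set input at 4 hpf differed by 0.28 (365 of 547 above that median, adjusted p = 0.0039). The difference at 2 hpf was -0.01 in footprints (270 of 547 above it, adjusted p = 0.49, test direction up) and that at 6 hpf in footprints was 0.97 (448 of 547 above it, adjusted p = 8.88e-21). At 2 hpf the median change of set input was -0.56, against -1.10 in other regions, so set input was lower in MZdicer but by less. That relative difference was 0.54 (366 of 547 above the median of other regions, adjusted p = 0.028 by camera). Set TE at 2 hpf was -0.48 relative to other regions (adjusted p = 0.050). Both rested on the sparse MZdicer library, with p = 0.63 and p = 0.62 under an estimated correlation. No order of footprints and mRNA was established. In wild type, set footprints fell by 0.91 from 2 to 4 hpf relative to other regions (adjusted p = 1.50e-08), a comparison that shares the wild-type 4 hpf libraries with that of genotypes and is not independent of it, and in MZdicer the difference was -0.31 (adjusted p = 0.27). With an estimated correlation these calls were lost, with unadjusted p = 0.18 for footprints at 4 hpf, p = 0.053 at 6 hpf, p = 0.53 for input at 4 hpf and p = 0.19 for wild-type footprints from 2 to 4 hpf. Without wild-type input at 6 hpf replicate 1, which helped select the set, the differences at 4 hpf were about equal, 0.28 in footprints and 0.25 in input, and that in footprints at 6 hpf was 0.55, and without MZdicer input at 4 hpf replicate 2 the input difference at 4 hpf was 0.10 and no longer called. Without MZdicer input at 4 hpf replicate 1 that difference was 0.48, nearer to the 0.61 in footprints, and without wild-type input at 4 hpf replicate 2 it was 0.18 and not called. The footprint difference at 2 hpf was 0.15 and called without wild-type replicate 2, and -0.16 and not called without wild-type replicate 1, so whether the set differed at 2 hpf rested on 1 library.

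**Figure D3:**
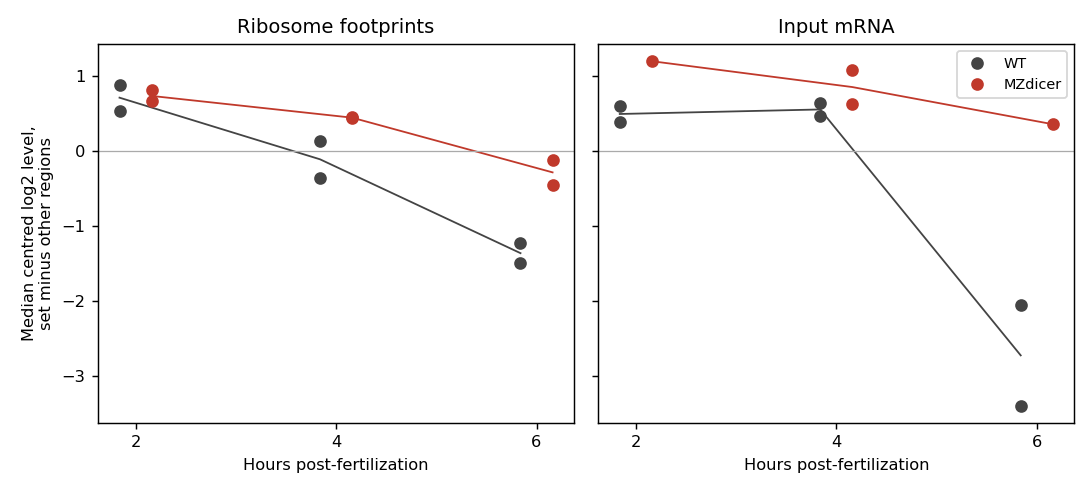
Median log2 level of the 547 regions higher in MZdicer input at 6 hpf minus that of other regions, each region centred on its mean, per library (points) with group means (lines), by hours post-fertilization, for wild type (grey) and MZdicer (red). Footprints of the set at 4 hpf stood at 0.44 and 0.45 in the MZdicer libraries and at -0.36 and 0.14 in wild type, and input at 6 hpf, which selected the set, stood apart by construction.

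Single regions of the set at 4 hpf seldom passed the test in footprints. Over all regions tested, 3 set regions passed 0.05, and 16 did so when adjusted over the set alone, which is not independent evidence because the set was chosen on these embryos. At the locus from 35931736 to 35939322 on chromosome 10, chosen after its values were seen, the median log2 change over 8 set regions was 2.03 in footprints and 0.14 in input at 4 hpf, and 3.22 in footprints and 3.08 in input at 6 hpf. At the locus from 569556 to 581841 on chromosome 23, with 7 set regions, the medians were 2.66 and -0.11 at 4 hpf and 2.69 and 3.92 at 6 hpf. The locus from 55443680 to 55455553 on chromosome 3, with 8 set regions, went the other way, with 0.40 in footprints and 0.83 in input at 4 hpf and -0.52 and 2.69 at 6 hpf. Of the 384 loci, 256 had a footprint median above 0 at 4 hpf and 241 had it above that of input, with no subtraction of the TE median of other regions. The set lower in MZdicer input at 6 hpf held 163 regions, against at most 129 expected by chance, so many of them may be there by chance. Its footprint differences were -0.24 at 4 hpf (adjusted p = 0.0025 by camera) and -0.47 at 6 hpf (adjusted p = 0.00022). Both calls were lost with an estimated correlation (p = 0.10 and p = 0.062).

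**Figure D4:**
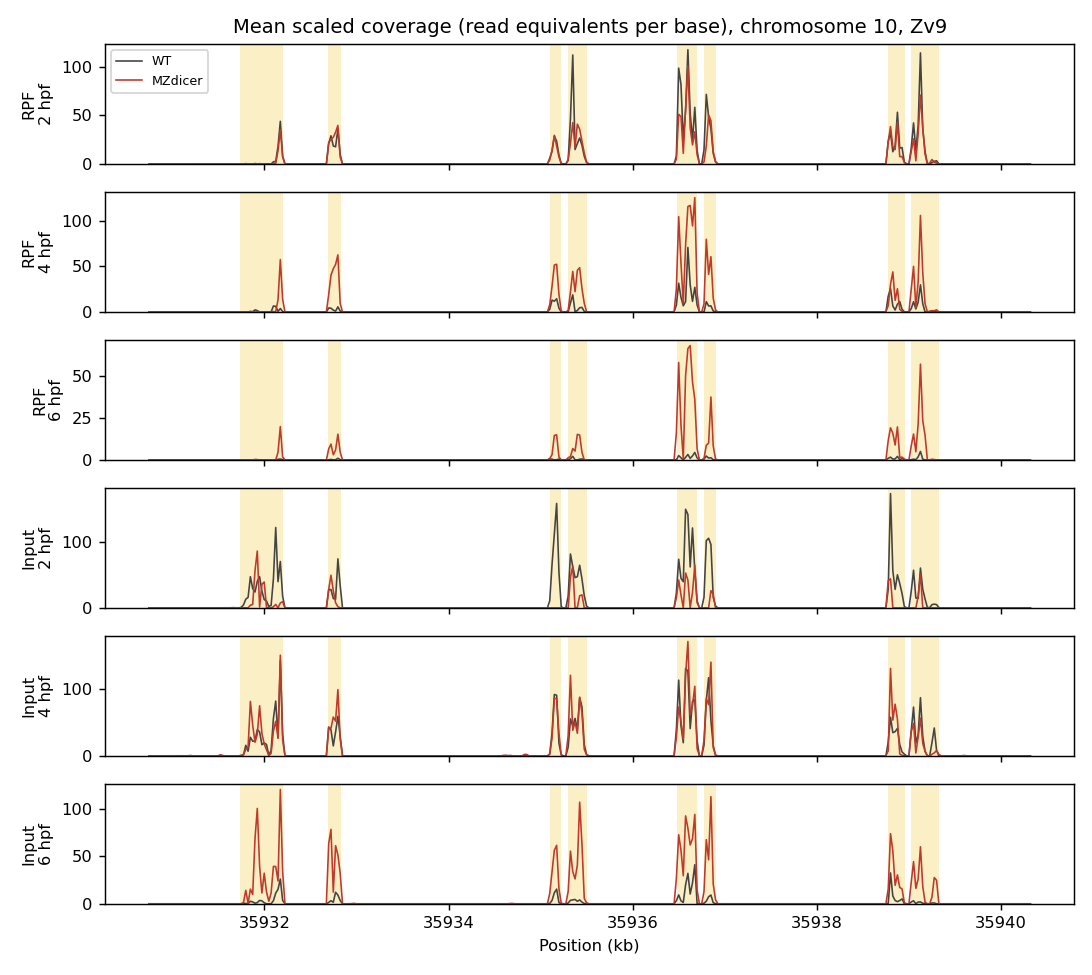
Mean scaled coverage in read equivalents per base along chromosome 10 from 35930736 to 35940322, in footprints (top 3 panels) and input (bottom 3 panels) at 2, 4 and 6 hpf, for wild type (grey) and MZdicer (red), with the 8 set regions shaded. At 4 hpf the median log2 change of the shaded regions was 2.03 in footprints and 0.14 in input.

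TE, the footprint change minus the input change, asks whether footprints changed beyond the level of polyA RNA. At 4 hpf, set TE was higher in MZdicer by 0.36 (333 of 547 regions above the median of other regions, which was 0.14, adjusted p = 0.023), a call lost with an estimated correlation (p = 0.57). The only single region called at 4 hpf, from 34590040 to 34590118 on chromosome 4, was lower, with footprints at 6.49 against 223 and input at 59.2 against 0, so the size of its change depends on the pseudocount. At 2 hpf, 2353 regions were higher and 107 lower, among them the chromosome 10 region from 22244570 to 22245330, whose MZdicer input was at 0 in the sparse library. With no filter on low values that balance was lost, with 892 higher and 1013 lower. At 6 hpf limma called 0 regions, with 1370 at an unadjusted p under 0.05 (387 higher and 983 lower) of 25723 tested. The set difference at 4 hpf was 0.01 without wild-type input at 6 hpf replicate 1, 0.09 without MZdicer input at 4 hpf replicate 1, 0.21 without wild-type input at 4 hpf replicate 1, 0.16 without wild-type footprints at 4 hpf replicate 1 and 0.60 without MZdicer input at 4 hpf replicate 2. The 1 call at 4 hpf, a lower one, became 177 higher and 13 lower without MZdicer input replicate 1. The count was 4 without wild-type input replicate 2 and 0 without wild-type input replicate 1, MZdicer footprints replicate 2 or wild-type footprints replicate 1, the 2460 calls at 2 hpf were 893 to 1599 without 1 library, and at 6 hpf there were 13 higher and 61 lower without MZdicer footprints replicate 1 and 2 higher without replicate 2.

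The time course in wild type asks how mRNA and footprints change across the onset of zygotic transcription. From 2 to 4 hpf, 227 input regions in 143 loci rose and 5 fell. The region from 64665014 to 64667393 on chromosome 5 rose from 2.02 to 721 (633 to 810; log2 change 7.69, SE 0.53), and its footprints went from 0 in both libraries to 317 (292 to 341), at least 320-fold higher. The regions from 31221962 to 31225338 on chromosome 22 (1.24 to 425, 7.16, SE 0.48), from 11969209 to 11972613 on chromosome 10 (1.82 to 478, 7.15, SE 0.45) and from 50778396 to 50781824 on chromosome 6 (1.12 to 408, 7.13, SE 0.44) also rose. Footprints of the last were 59.1 (26.0 to 92.3) at 2 hpf and 36.4 (25.2 to 47.5) at 4 hpf. Its TE change was -7.62 (SE 0.96), but its mean input at 2 hpf lay under the floor, so that size depends on the pseudocount. The region from 27616595 to 27620057 on chromosome 21 had almost the same wild-type footprints at 2 hpf (26.3 to 92.3). Reads placed at both regions could not be excluded. Among 182 input-rising regions also tested in footprints, 77 were called higher there, against 0.849 expected. The set as a whole rose 10.5-fold relative to other regions in wild-type footprints (180 of 182 above the median of other regions and 171 above 0, p = 0.00021 with an estimated correlation) and 10.8-fold in MZdicer footprints (180 of 182 above that median, p = 0.00017). Only 35 of the 182 (19.2%) had at least 10 scaled read equivalents in wild-type input at 2 hpf. Regions low at 2 hpf could pass the filter on footprint levels through libraries of 4 or 6 hpf. Part of this rise, in both genotypes, may thus be fixed by that filter. The 232 input calls were 102 without replicate 1 at 4 hpf, 96 without replicate 2 at 4 hpf and 0 in a fit of the compared groups alone, and 3601 regions had an unadjusted p under 0.05 with limma. With no filter on low values 547 rose and 740 fell.

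Footprints in wild type rose in 168 regions and fell in 35 from 2 to 4 hpf. Repeated regions on chromosome 2 rose, such as that from 14523427 to 14523553 (1.45 to 563, 7.0, SE 0.82), as did regions with shared profiles on chromosome 4 within 28004616 to 28016606, such as that from 28008747 to 28008974 (4.14 to 656, 6.70, SE 0.65). The region from 27745193 to 27747826 on chromosome 20 fell from 50.2 to 0.470 (-4.41, SE 0.78). In MZdicer, 119 footprint regions rose and 17 fell. On the deposited scale the counts were 28 and 1 in wild type and 11 and 5 in MZdicer. The genotype difference of the change was called in 0 regions by limma, with 896 at an unadjusted p under 0.05. TE changed in 4 regions, 1 higher and 3 lower, and the higher one, from 21924783 to 21924864 on chromosome 22, gave 6.61 (SE 1.06). There were 8 higher and 6 lower without input at 2 hpf replicate 2, 5 and 2 without input at 4 hpf replicate 2, and 2 and 6 without footprints at 4 hpf replicate 2.

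From 4 to 6 hpf, 5186 input regions in 2354 loci rose in wild type and 2399 in 1531 loci fell. The region from 52890420 to 52893441 on chromosome 1 went from 0 to 1597 (1463 to 1730), at least 571-fold higher, and that from 18534428 to 18536477 on chromosome 14 from 0 to 1140, at least 407-fold higher. The region from 55787731 to 55788066 on chromosome 20 rose in input from 1.75 to 1447 (8.69, SE 1.04) and in footprints from 2.16 to 985 (7.87, SE 0.76). The region from 4981513 to 4983491 on chromosome 21 fell from 184 (167 to 201) to 1.25 (-5.95, SE 0.67). The 7585 calls split into 2684 higher and 4035 lower on the deposited scale, where the median change moved from -0.10 to -0.65. They numbered 924 without replicate 1 at 4 hpf, 1552 without replicate 2 at 4 hpf and 3377 without replicate 2 at 6 hpf.

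Footprints moved with input from 4 to 6 hpf. In wild type 1231 footprint regions rose and 366 fell, and in MZdicer 863 rose and 452 fell. Of 2209 regions that rose in wild-type input and were tested in both types, 812 also rose in wild-type footprints, against 97.8 expected if independent, and of 1464 that fell in input, 144 fell in footprints, against 19.9. As a set the rising regions were 5.35-fold higher relative to other regions in wild-type footprints (2128 of 2209 above the median of other regions and 2104 above 0, p = 2.19e-05 with an estimated correlation) and 4.09-fold higher in MZdicer footprints (2077 of 2209 above that median, p = 4.77e-05). The falling regions stood at 0.375-fold in wild type and 0.430-fold in MZdicer, with p = 0.028 and p = 0.059 under an estimated correlation, neither of which passed when adjusted over the 41 tests (adjusted p = 0.23 and adjusted p = 0.32), while the rising regions did (adjusted p = 0.00090 and adjusted p = 0.00098). Input rose in these regions by selection. The footprint libraries entered it only through the filter of at least 10 read equivalents in at least 2 of them. A region low at 4 hpf could pass that filter through its 6 hpf footprints, so part of the footprint rise may be fixed by it. Among the rising regions, 641 lay under 1 scaled read equivalent in wild-type input at 2 hpf. Of these, 99.5% and 99.4% reached 2 in wild-type footprints at 6 hpf, against 21.1% and 20.6% at 4 hpf. The genotype difference of the footprint change was called in 0 regions by limma, with 2098 at an unadjusted p under 0.05, and TE changed in 0 regions in wild type, with 1990 at an unadjusted p under 0.05. With the deposited scale the footprint counts were 130 and 1 in wild type and 100 and 6 in MZdicer, and with median-of-ratios scaling 690 and 571 in MZdicer. The TE count was 7 without input at 6 hpf replicate 1 and 1 without footprints at 6 hpf replicate 1.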

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

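The set of regions higher in MZdicer input at 6 hpf and the tests of explanations for its footprints were chosen after the results were seen. The genotype difference of set footprints was larger at 4 hpf than at 2 hpf by 0.53 (log2, 381 of 547 regions above the median of other regions, adjusted p = 1.09e-06) and larger at 6 hpf than at 4 hpf by 0.48 (347 of 547 above that median, adjusted p = 0.0033), each by a test of the difference between stages. The 2 hpf difference itself ran from -0.16 to 0.15 with 1 library left out. Both calls were lost with an estimated correlation (p = 0.24 and p = 0.45).

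At 4 hpf the footprints of the set were higher in MZdicer by more (0.61) than its input (0.28). An input rise hidden by the sparse MZdicer input replicate 2 was argued against, since without that library the input difference was smaller, 0.10 (0.48 without replicate 1), and compression by the pseudocount was argued against, since among 86 set regions with a mean of at least 50 the input difference was 0.0938 and the footprint difference 0.90. Several regions of 1 locus carrying the TE difference stayed open, since with 1 region per locus it was 0.20, above 0.5 of 0.36, and was no longer called. Chance between few libraries whose regions vary together stayed open too, since the TE difference had p = 0.57 with an estimated correlation. That ribosome occupancy differed between genotypes ahead of mRNA level is a hypothesis these data prompted. It was not tested on its own and cannot be told apart from those 2 open explanations, or from others that were not tested. It also rests on how the set was selected, since without wild-type input at 6 hpf replicate 1 the set TE difference was 0.01. The set fell in wild-type input from 4 to 6 hpf (median -3.02). All regions that fell then also stood 0.25 higher in MZdicer footprints at 4 hpf (p = 0.44 by camera with an estimated correlation), and those that rose differed by 0. The 2 hpf values gave the hypothesis no support and cannot decide it. There, set input stood 0.54 higher relative to other regions in a sparse library (median change -0.56 against -1.10), and footprints differed by -0.01.

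The mitochondrial share of coverage, which the comparisons did not use, lay above both wild-type libraries of the same type and stage in 3 MZdicer libraries. It was 13.7% in input at 2 hpf, 18.3% in input at 6 hpf and 1.66% in footprints at 6 hpf replicate 1, where replicate 2 had 0.401%.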

How the results depend on the processing

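Settings chosen after the data were seen were the deposited scale, the pseudocounts, the prior, library weights, loci, removal of sparse libraries, and everything on the set. Of 387 recomputed values, 246 were counted as kept. A count of calls had to stay within 1.5 times the main count, which takes no note of the split into higher and lower calls. A set difference had to keep its side of the threshold, and its direction was checked only where 1 of the p-values compared was under 0.05. The uncalled set difference in footprints at 2 hpf thus counted as kept from -0.16 to 0.16. Wild-type input from 4 to 6 hpf kept its count in 14 of 17 settings (5662 to 10680), and the set difference in footprints kept its call in 22 of 25 settings at 4 hpf (0.28 to 1.63) and 23 of 25 at 6 hpf (0.55 to 2.46). Nearly all of these set settings kept the preset correlation, and the call was lost with an estimated one (p = 0.18 at 4 hpf and p = 0.053 at 6 hpf). The changes listed here are counts of calls between genotypes unless wild type (4 against 2, or 6 against 4 hpf) is named, and the cause was not tested. The DESeq2 test, miR-430 site definitions, matched comparison genes and input over all exons were not run. Sparse libraries and single-library groups limit depth.

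On the deposited scale there were 3 calls in footprints at 2 hpf, 16 at 4 hpf and 0 at 6 hpf, 11 in input at 4 hpf and 120 at 6 hpf, 175 in TE at 2 hpf and 1 at 6 hpf, 1 in wild-type TE 4 against 2 hpf, and a set TE difference of 0.28 at 4 hpf, not called. Median-of-ratios scaling gave 36 in footprints at 6 hpf. A pseudocount of 0.5 gave 18 in footprints at 4 hpf and 26 at 6 hpf, 12758 in input at 2 hpf, 1 at 4 hpf and 19 at 6 hpf, 3 in TE at 4 hpf and 1 in wild-type TE 4 against 2 hpf. A pseudocount of 8 gave 3958 in input at 2 hpf, 2 in TE at 6 hpf, and 8 and 19 in wild-type TE 4 against 2 and 6 against 4 hpf. A prior that was not robust gave 0 in input at 4 hpf and 2 at 6 hpf. Library weights gave 62 in footprints at 4 hpf and 3 at 6 hpf, 33508 in input at 2 hpf and 1 at 4 hpf, 5858 in TE at 2 hpf, and 1383 in wild-type input and 11 in wild-type TE 4 against 2 hpf.

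Distinct left ends gave 0 in footprints at 2 hpf and 2 at 4 hpf, 24 in input at 4 hpf and 298 at 6 hpf, 763 in TE at 2 hpf, 0 at 4 hpf and 3 at 6 hpf, and 372 in wild-type input and 1 in wild-type TE 4 against 2 hpf. Loci gave 15 in footprints at 4 hpf and 86 at 6 hpf, 4935 in input at 2 hpf and 125 at 6 hpf, 1423 in TE at 2 hpf and 8 in wild-type TE 4 against 2 hpf. With no filter on low values there were 3 in footprints at 2 hpf, 0 at 4 hpf and 0 at 6 hpf, 5801 in input at 2 hpf, 550 at 4 hpf and 155272 at 6 hpf, 1905 in TE at 2 hpf, 0 at 4 hpf and 5336 at 6 hpf, 1287 in wild-type input and 0 in wild-type TE 4 against 2 hpf, and 205 in wild-type TE 6 against 4 hpf. Its set of 6871 regions differed by 0 in footprints at 4 and 6 hpf, 0 in input and 0 in TE at 4 hpf (test direction down), and by 0.10 in wild-type footprints from 2 to 4 hpf, the reverse of -0.91.

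A fit of the compared groups alone gave 0 in footprints at 2, 4 and 6 hpf, 21609 in input at 2 hpf and 0 at 4 and 6 hpf, 4370 in TE at 2 hpf and 2 at 6 hpf, and 0 in wild-type input and 0 in wild-type TE 4 against 2 hpf. Without the sparse libraries of groups of 2 (MZdicer input at 4 hpf replicate 2 and footprints at 6 hpf replicate 2, while the sparse MZdicer input at 2 hpf stayed in) there were 66 in footprints at 4 hpf and 7 at 6 hpf, 13329 in input at 2 hpf, 0 at 4 hpf and 6 at 6 hpf, 4657 in TE at 2 hpf and 2 at 6 hpf, and a set input difference of 0.0943 at 4 hpf. The differences between replicates 1 and 2 were correlated across regions between groups, to see whether samples of equal replicate number varied together. These correlations of differences were -0.05 to 0.15 in 6 input pairs, -0.23 to 0.15 in 15 footprint pairs and -0.0866 to 0.0304 in 4 pairs of footprints with input. They lay above 0.1 in 1 input pair and 2 footprint pairs, so samples of equal number mostly did not vary together. A replicate block gave 33 in footprints and 1 in TE at 6 hpf, 12 in input at 4 hpf and 3 in wild-type TE 6 against 4 hpf.

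With an estimated correlation the set differences had the same size but no call, 0.61 in footprints at 4 hpf, 0.97 at 6 hpf, -0.91 in wild-type footprints from 2 to 4 hpf (p = 0.19), 0.28 in input (p = 0.53) and 0.36 in TE at 4 hpf (p = 0.57). One region per locus gave a TE difference of 0.20. The 54 regions with an adjusted p under 0.05 gave 0.16 in footprints at 2 hpf, now called but not with an estimated correlation (p = 0.42), and with an estimated correlation 1.63 in footprints, 0.47 in input and 0.96 in TE at 4 hpf and -1.41 in wild-type footprints, none called, while footprints at 6 hpf gave 2.46 (p = 0.0083).

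Leaving out 1 library gave 1 to 12 calls in footprints at 2 hpf, 0 to 9 at 4 hpf and 0 to 2086 at 6 hpf, 3064 to 3425 in input at 2 hpf, 0 to 252 at 4 hpf and 1 to 19 at 6 hpf, 893 to 1599 in TE at 2 hpf, 0 to 190 at 4 hpf and 0 to 74 at 6 hpf. In wild type it gave 96 to 239 in input and 3 to 14 in TE for 4 against 2 hpf, and 924 to 7156 and 0 to 7 for 6 against 4 hpf. Set differences were -0.16 to 0.15 in footprints at 2 hpf, 0.28 to 0.87 at 4 hpf, 0.55 to 1.29 at 6 hpf, 0.10 to 0.48 in input and 0.00923 to 0.60 in TE at 4 hpf, and -1.14 to -0.62 in wild-type footprints from 2 to 4 hpf. A lone remaining library was assumed to vary like the other groups.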

Other observations

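The tests on the wild-type footprint library and on persistence across stages were chosen after the results were seen, and that on the 2 hpf input calls was set before its result was seen. Among the regions that rose in wild-type input from 4 to 6 hpf, 641 lay under 1 scaled read equivalent in wild-type input at 2 hpf and were tested in both types. Their footprints at 4 hpf summed to 4.47% and 3.69% of the wild-type 6 hpf level in wild type and to 3.74% and 3.59% in MZdicer. At 6 hpf the MZdicer footprint libraries stood at 72.1% and 83.9% of that level, and MZdicer input stood at 60.1% of wild-type input, which had selected the regions. These differences were not tested. Of 40 loci with 3 or more set regions, 32 had a footprint median above that of input at 4 hpf, such as that from 60290813 to 60300383 on chromosome 1 (2.06 and -0.34), and others had the reverse, such as that from 55443680 to 55455553 on chromosome 3 (0.40 and 0.83). The TE median of other regions, 0.14, was not subtracted. The loci are not all separate, since that from 25379797 on chromosome 23 and that from 31830616 on chromosome 2 had the same footprint medians (2.41 at 4 hpf and 2.97 at 6 hpf).

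MZdicer input at 2 hpf had 7448 lower calls, and its few distinct left ends were weighed as the source, with each wild-type library at this stage thinned to 91538 distinct left ends and set against the other in place of the MZdicer library. The thinned libraries gave 1155 and 1879 lower calls where the MZdicer library gave 2847 and 3238, ratios of 0.406 and 0.580. The median change was -0.88 and -0.77 with the thinned libraries, against -1.51 and -1.45. Of the regions tested, 52.6% and 49.4% were at 0 in them, against 60.2%. The regions tested numbered 78586 and 77877 with the thinned libraries and 90008 with the MZdicer library. Few distinct left ends could thus account for part of the calls. Whether they account for all of the shift cannot be told, since thinning matched only the number of left ends. The wild-type libraries had 8.21 and 9.86 reads per left end, against 54.9 in the MZdicer library, and other regions were tested. The share of depth cannot be told apart, since the group holds 1 library and the smaller ratio, 0.406, lay between the bounds set in advance. A difference between the genotypes stays open as untested.

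Wild-type footprints at 2 hpf replicate 2 stood apart, with 1045318 distinct left ends, 3.73% mitochondrial coverage and a scaling factor of 4.91, against 643884, 0.842% and 2.19 in replicate 1. Reads of 6 hpf were argued against as the cause, since the summed level of the 641 late-rising regions was 0.451% of that at 6 hpf, against 0.894% in replicate 1. Of these regions 6 reached 2 scaled read equivalents in replicate 2 and 10 in replicate 1, a ratio of 0.6. That cutoff takes more reads in replicate 2, by its larger scaling factor, so the ratio leans toward replicate 1. Reads of 4 hpf stayed open, since wild-type footprints at 4 hpf themselves held only 4.47% and 3.69% of the 6 hpf level in these regions. Reads of input of the same stage stayed open too and were not tested. The highest correlation of replicate 2 across regions with an input library was r = 0.684, with wild-type input at 2 hpf. It was r = 0.548 in replicate 1 and up to r = 0.666 in other footprint libraries. Regions are not independent replicates. No biological explanation was tested for this library.

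One hypothesis for the regions called between genotypes in footprints at 4 hpf was a difference between the strains or repeat copies that does not change with stage. Of 24 distinct profiles called, 17 had the same direction at 2 and 6 hpf (9 of 14 higher ones and 8 of 10 lower ones), a share of 70.8%, which fell between the bounds of 75% and 50% set for the test, so the hypothesis stayed open. Of 8 profiles with enough input, 6 had the same direction in input at 4 hpf.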
